A study of Homo sapiens with 8 samples.

How the data were processed

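Binding of the tumour suppressor p53 to the genome was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in U2OS, a human osteosarcoma cell line that, per the labels' protocols, carries wild-type p53. Cells received no treatment, 0.1% DMSO, 0.6 µg/ml doxorubicin or 10 µM Nutlin-3, with a time of 24 h listed for every condition. Per the labels' protocols, chromatin was fixed with formaldehyde, sheared and precipitated with the p53 antibody DO-1, and libraries were made with an Illumina ChIP-seq kit. Each condition had 1 ChIP library and 1 input library. The labels name no treatment as the control of doxorubicin and DMSO as the control of Nutlin-3.

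The authors deposited a list of peaks for each of the 4 ChIP libraries, and no list of peaks for the 4 inputs was used here. Each list holds 3 columns, a chromosome, a start and an end, with no score, height, enrichment, p-value or read count for a peak. The submitters' processing notes name the build hg18, the software CASAVA and the aligner Bowtie 0.12.2. What each did is not given in the sources used here. Per the labels, inputs served as controls; how they were used, the peak caller, its threshold and its filters are not given in the sources used here. There was a list for each library, with no pooled list. All 24535 peaks had widths that were multiples of 20 bp, no start ended in a digit other than 1, and 0 pairs of peaks overlapped within a list. The values thus sit on a fixed grid, and a position is known to about 20 bp. Positions are given as deposited. Whether starts count from 0 or from 1, and whether the end belongs to the peak, is not stated, which leaves 1 bp open. The number of reads behind each list is unknown, so the depth could not be set beside the number of peaks, and lists of different length can differ in depth, in enrichment or in binding.

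The files held positions and no scores, so the planned steps were adapted as follows. Peaks were ranked by width where a rank was planned by score. Peaks could not be assigned to genes, promoters or p53 motifs, because no genome or annotation of hg18 was used here and positions were not converted between builds. The 10 gene lists fixed in advance (targets of p53 in cell cycle arrest, apoptosis, DNA repair, feedback, metabolism and autophagy, matrix and adhesion, and innate immunity, with bone lineage, housekeeping and silent genes as controls) therefore gave no result. Regions are named by their coordinates in hg18.

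Overlap between lists was computed with bedtools 2.31.1 and Python 3.11.15 (numpy 2.4.6, scipy 1.17.1), and a peak counted as shared when it had at least 1 bp in common with a peak of the other list. The end was taken to lie outside the peak, so adjoining peaks, where an end equals a start, did not count as shared. If ends belong to the peak, such pairs share 1 bp and the shares would be higher. The number of such pairs is not given here. Each direction is given as a percentage of the peaks of a list, for all 12 ordered pairs of lists, with an exact 95% binomial interval (Clopper-Pearson). Such an interval covers counting error only and treats peaks as independent. The level that chance gives came from 100 shuffles, in which each peak of a list was put at a random place between the first and the last peak of its chromosome in any list. A stricter chance level, added after the data were seen, moved each peak by 5 to 50 kb in either direction. Overlapping or adjoining peaks of the 4 lists were merged into regions, and each region was counted by the lists it held. Regions thus also join adjoining peaks that the shares count as not shared. The widths of shared peaks were compared with those of 10000 random sets of peaks of the same list. With 1 library per condition there is no replicate, so no test of a difference between conditions was made and no p-value is given.

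The text names, by a rule fixed before the data were examined, the 10 widest peaks of each list, the regions found in all 4 lists, and for each treatment the 10 widest peaks found neither in its own control nor in the other treatment. The first 3 of each part are given in full. Dense stretches were defined after the data were seen as runs of at least 5 peaks of a list with gaps of at most 20 kb. The overlap code was tested on simulated data in which 5%, 30% and 70% of 1000 peaks with DMSO widths were placed on Nutlin-3 peaks, and it found 5%, 30% and 70%.

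Alternatives fixed in advance were a reciprocal overlap of at least 50%, midpoints within 200 bp, peaks within 1000 bp, the widest 50% of each list, the same number of widest peaks in each list (496), autosomes alone, and merging of peaks up to 500 bp apart. Alternatives added after the data were seen removed chromosomes M and Y and the dense stretches of the untreated list, used DMSO as the control of doxorubicin, or left out a control list. Peaks above a common score and the leaving out of a replicate could not be run.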

Results

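The data comprised 4 lists of p53 ChIP-seq peaks from U2OS osteosarcoma cells, with 1 library per condition and no replicates. Doxorubicin is a topoisomerase II poison that breaks DNA and so activates p53. Nutlin-3 is a small molecule that keeps the ubiquitin ligase MDM2 from binding p53 and stabilises p53 without damaging DNA. The untreated cells had 496 peaks, the cells given the solvent DMSO had 2793, the doxorubicin-treated cells had 3087 and the Nutlin-3-treated cells had 18159. The peaks covered 96.8 kb, 228 kb, 347 kb and 1610 kb of the genome in the same order. The median width was 60 bp in each list, and peaks of the smallest width, 40 bp, made up 34.6% of the Nutlin-3 list and 47.5% of the DMSO list. The number of reads behind the lists is unknown, so list lengths describe these libraries and their peak calling as well as the binding.

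Merging the lists gave 19877 regions, of which 3174 were found in at least 2 lists and 16703 in 1 list alone. Nutlin-3 alone accounted for 15116 regions, or 76.0% of the total. The next most frequent class, with 1400 regions, held DMSO, doxorubicin and Nutlin-3 peaks and no peak from untreated cells. Doxorubicin and Nutlin-3 shared a further 794 regions that were in neither control, and DMSO and Nutlin-3 shared 775 that were in no other list. Only 6 regions were found in all 4 lists.

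**Figure D1:**
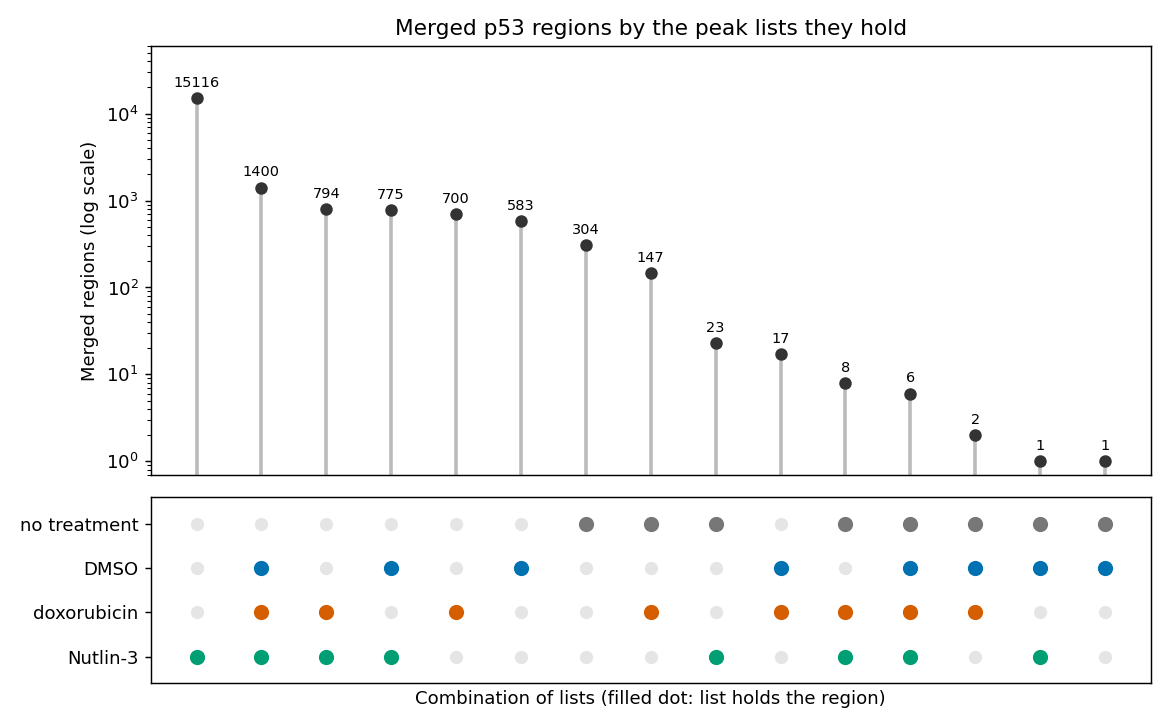
Number of merged p53 regions (log scale) for each of the 15 combinations of the 4 peak lists; filled dots below the points mark the lists that hold the regions. The Nutlin-3 list alone held 15116 regions, and the combination of DMSO, doxorubicin and Nutlin-3 held 1400.

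Most p53 sites listed after DNA damage by doxorubicin were not listed in untreated cells. Of the doxorubicin peaks, 40.6% did overlap a peak of DMSO, the control of Nutlin-3. Doxorubicin gave 6.22 times as many peaks as no treatment and 3.58 times the covered length. Of the 3087 doxorubicin peaks, 2916 (94.5%) had no counterpart in untreated cells, while 171 (5.54%, 95% interval 4.76 to 6.41) overlapped one. In the other direction, 166 of the 496 untreated peaks (33.5%, 29.3 to 37.8) were overlapped by a doxorubicin peak, against a mean of 3.13 and a highest value of 8 in 100 shuffles, and a mean of 13.2 and a highest value of 22 after local moves of 5 to 50 kb. The 166 had a median width of 220 bp and the other 330 untreated peaks one of 60 bp, and 0 of 10000 random sets of untreated peaks reached the former. The random sets drew peaks as if independent, although 106 of the 166 lay in dense stretches (described below) or on chromosomes M or Y. Wider peaks also have more room to overlap. The smallest were shared too: doxorubicin overlapped 29.9% of untreated peaks of 40 bp (56 peaks), 4.17% of those of 60 bp and 70.8% of those of at least 300 bp.

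Many of the sites common to untreated and doxorubicin-treated cells lay in dense stretches. The untreated list had 15 such stretches, with 147 of its peaks in 352 kb in all. The fullest, on chromosome 16 from 44943411 to 44993051, held 30 untreated and 43 doxorubicin peaks and 0 peaks from DMSO or Nutlin-3. A stretch on chromosome 2 from 90959451 to 90983811 held 16 untreated and 14 doxorubicin peaks, again with 0 from the other lists. A further stretch, on chromosome 2 from 91125631 to 91184311, held 16 untreated, 11 doxorubicin, 0 DMSO peaks and 1 Nutlin-3 peak. Over the 15 stretches, doxorubicin had 169 peaks, Nutlin-3 had 15 and DMSO had 2. Chromosome M carried 12 untreated peaks, 2 doxorubicin peaks and 0 peaks from DMSO or Nutlin-3, and chromosome Y carried 25 untreated, 104 doxorubicin, 0 DMSO and 7 Nutlin-3 peaks. Of the 149 untreated peaks in the stretches or on chromosomes M or Y, 106 (71.1%, 63.2 to 78.3) were overlapped by doxorubicin. Of the 347 peaks elsewhere, 60 (17.3%, 13.5 to 21.7) were. The median width was 260 bp in these places and 60 bp elsewhere. Without these stretches and chromosomes, 2.24% of doxorubicin peaks overlapped an untreated peak.

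**Figure D2:**
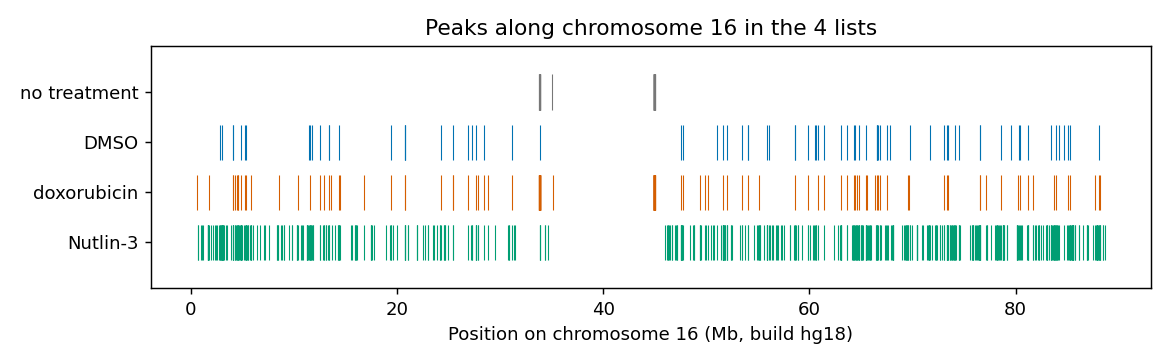
Peaks along chromosome 16 (Mb, build hg18) in the 4 lists, with 1 line per peak. Untreated peaks stood in a few places beside a peak-free interval, among them the stretch that begins at 44943411, and doxorubicin peaks crowded in the same places (43 between 44 and 45 Mb and 27 between 33 and 34 Mb) besides others along the chromosome, as with DMSO and Nutlin-3.

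The widest untreated peak, of 2840 bp, lay on chromosome 6 from 58884471 to 58887311 and had the same bounds in the doxorubicin list, with no peak in DMSO or Nutlin-3. The next were on chromosome 9 from 67902311 to 67904311 (2000 bp, in all 4 lists) and on chromosome M from 1251 to 3131 (1880 bp, in no other list). Among the 10 widest untreated peaks, 9 were overlapped by doxorubicin, 3 by Nutlin-3 and 2 by DMSO. The widest doxorubicin peak lay on chromosome Y from 57386271 to 57389611 (3340 bp), followed by chromosome 19 from 32427751 to 32430771 (3020 bp) and the same chromosome 6 peak. Of the 10 widest doxorubicin peaks, 5 were overlapped by untreated peaks, 0 by DMSO and 1 by Nutlin-3.

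The Nutlin-3 list held many p53 sites that were not listed with its solvent. It had 6.50 times as many peaks as the DMSO list and 7.06 times the covered length. Most DMSO sites were found again: 1967 of 2793 DMSO peaks (70.4%, 68.7 to 72.1) were overlapped by a Nutlin-3 peak, against a highest value of 7 in 100 shuffles and 17 after local moves. A further 502 DMSO peaks (18.0%) lay within 1000 bp of a Nutlin-3 peak without overlapping it, adjoining peaks included. With a reciprocal overlap of at least 50% the share of DMSO peaks found again was 40.5%. From the side of Nutlin-3, 1982 of 18159 peaks (10.9%, 10.5 to 11.4) overlapped a DMSO peak and 16177 (89.1%) did not. Merged regions with Nutlin-3 and without DMSO numbered 15941.

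The widest DMSO peaks were on chromosome 15 from 61235351 to 61236051 (700 bp, also in Nutlin-3), on chromosome 6 from 151219931 to 151220551 (620 bp, also in doxorubicin and Nutlin-3) and on chromosome 4 from 40842051 to 40842651 (600 bp, also in Nutlin-3). Of the 10 widest DMSO peaks, 9 were overlapped by Nutlin-3, 4 by doxorubicin and 0 by untreated peaks. The widest Nutlin-3 peaks were on chromosome 2 from 132729031 to 132730011 (980 bp) and on chromosome 16 from 33870111 to 33870971 (860 bp), both inside dense stretches of the untreated list, and on chromosome 17 from 54124711 to 54125491 (780 bp). Of the 10 widest Nutlin-3 peaks, 7 were overlapped by doxorubicin, 4 by DMSO and 3 by untreated peaks.

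The fullest dense stretch of the DMSO list lay on chromosome 6 from 36742591 to 36758811, a span of 16.2 kb. It held 11 DMSO, 5 doxorubicin and 13 Nutlin-3 peaks and 0 untreated peaks. The peak from 36752211 to 36752251, which is 40 bp wide, had the same bounds in DMSO, doxorubicin and Nutlin-3. The Nutlin-3 peak from 36753651 to 36754271 was 620 bp wide, and the DMSO peak inside it, from 36753691 to 36753871, was 180 bp wide. This stretch was chosen after its values were seen.

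**Figure D3:**
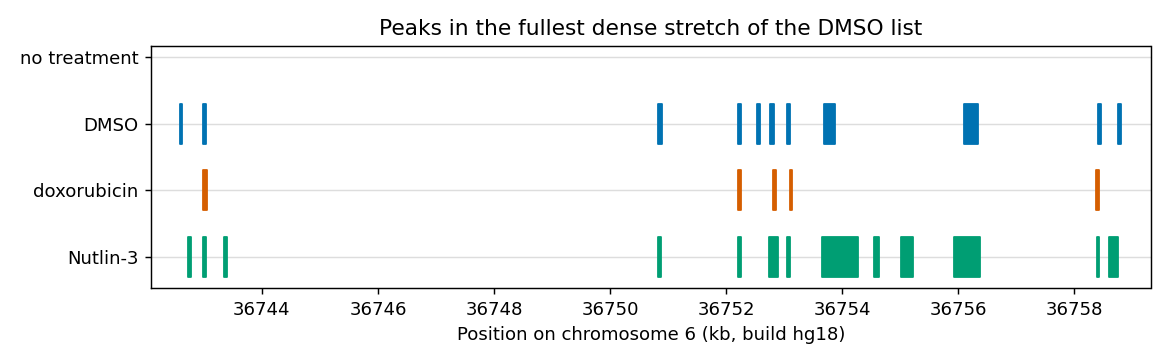
Peaks drawn to scale in the chromosome 6 stretch from 36742591 to 36758811 (kb, build hg18), with a line per list. DMSO had 11 peaks, doxorubicin 5 and Nutlin-3 13, and the untreated line is empty.

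By an overlap of at least 1 bp, doxorubicin and Nutlin-3 shared most doxorubicin sites and few Nutlin-3 sites. Of the 3087 doxorubicin peaks, 1959 (63.5%, 61.7 to 65.2) were overlapped by Nutlin-3, against a highest value of 9 in 100 shuffles and 18 after local moves. The share was 33.7% with a reciprocal overlap of at least 50% and 78.1% within 1000 bp. The Nutlin-3 list was 5.88 times as long, and 1967 of its peaks (10.8%, 10.4 to 11.3) overlapped doxorubicin. Of the 2208 regions that both treatments held, 1406 were also found with DMSO. Doxorubicin peaks found with DMSO and those found in untreated cells differed in this. Of the 1254 doxorubicin peaks that overlapped a DMSO peak, 1127 (89.9%, 88.1 to 91.5) were in the Nutlin-3 list, against 12 of the 171 that overlapped an untreated peak (7.02%, 3.68 to 11.9) and 824 of the 1669 in neither control (49.4%, 46.9 to 51.8). Outside the dense stretches and chromosomes M and Y, 8 of 64 doxorubicin peaks that overlapped an untreated peak were in the Nutlin-3 list (12.5%, 5.55 to 23.2). For Nutlin-3 peaks the shares found with doxorubicin were 57.7% (55.5 to 59.9) of the 1982 overlapped by DMSO, 29.4% (15.1 to 47.5) of the 34 overlapped by untreated peaks and 5.06% (4.73 to 5.41) of the 16147 in neither control. The split by control was made after the data were seen.

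Peaks found neither in the own control nor with the other treatment numbered 969 for doxorubicin (31.4% of its list) and 15353 for Nutlin-3 (84.5%). The widest doxorubicin peaks of this class were on chromosome Y from 57389891 to 57391631 (1740 bp) and from 57392891 to 57394611 (1720 bp), and on chromosome 2 from 132735251 to 132736851 (1600 bp), all inside dense stretches of the untreated list. The widest Nutlin-3 peaks of this class were on chromosome 17 from 54124711 to 54125491 (780 bp, overlapped by an untreated peak), on chromosome 4 from 124972731 to 124973371 (640 bp) and on chromosome 18 from 3973331 to 3973931 (600 bp). Among regions held by both treatments and by neither control, the widest were on chromosome Y from 11935831 to 11937211 (1380 bp, inside a dense stretch of the untreated list), on chromosome 2 from 240293631 to 240294431 (800 bp) and on chromosome 22 from 28922211 to 28922931 (720 bp). Among regions held by DMSO, doxorubicin and Nutlin-3, the widest were on chromosome 19 from 34850771 to 34851631 (860 bp), chromosome 6 from 151219931 to 151220671 (740 bp) and chromosome 1 from 231381971 to 231382671 (700 bp). The regions of the last 2 classes were picked after the data were seen.

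Width did not rank the sites by how often they were shared. Nutlin-3 peaks of 40 bp were overlapped by DMSO in 17.2% of cases (16.3 to 18.1), those of 60 bp in 5.65% (5.01 to 6.34) and those of at least 300 bp in 17.6% (14.3 to 21.3). Shares with doxorubicin were 16.5%, 6.21% and 19.1% in the same order. DMSO peaks of at least 300 bp were overlapped by Nutlin-3 in 90.9% (81.3 to 96.6) and those of 40 bp in 68.6% (66.0 to 71.1). Doxorubicin peaks went the other way between these classes, with 18.2% (13.2 to 24.2) of those of at least 300 bp and 64.3% (61.6 to 66.8) of those of 40 bp overlapped by Nutlin-3. In between, the share was highest at 80 to 100 bp, with 77.4% (72.1 to 82.2). Untreated peaks overlapped 38.9% (32.2 to 46.0) of the 203 doxorubicin peaks of at least 300 bp, against 3.72% of those of 40 bp. Identical bounds in DMSO, doxorubicin and Nutlin-3 occurred for 56 peaks, all 40 bp wide.

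**Figure D4:**
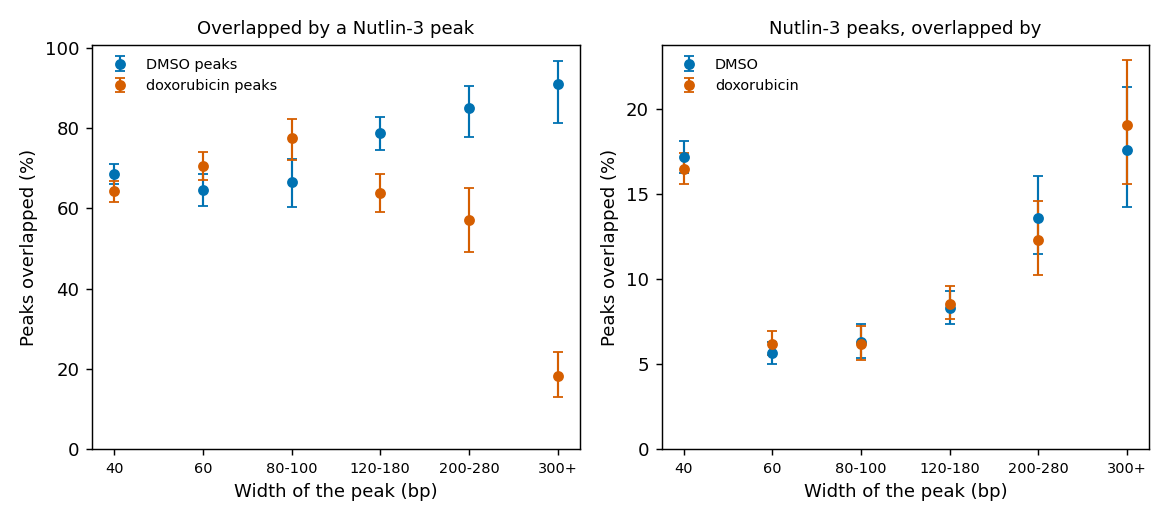
Percentage of peaks overlapped by another list, by the width of the peak in bp; points are values of the lists and bars exact 95% binomial intervals. Left, DMSO and doxorubicin peaks overlapped by Nutlin-3, which diverge from 120 bp upwards and reach 90.9% and 18.2% at 300 bp and more; right, Nutlin-3 peaks overlapped by DMSO or doxorubicin, which are lowest at 60 to 100 bp.

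The control conditions, which the labels separate by the solvent, shared few sites. DMSO gave 5.63 times as many peaks as no treatment. Only 6 of 496 untreated peaks (1.21%, 0.445 to 2.61) overlapped a DMSO peak, and 6 of 2793 DMSO peaks (0.215%, 0.0789 to 0.467) overlapped an untreated one. The highest value in either direction was 2 peaks in 100 shuffles and 3 after local moves. DMSO peaks were instead found with doxorubicin in 1256 cases (45.0%, 43.1 to 46.8), and 1254 doxorubicin peaks (40.6%, 38.9 to 42.4) overlapped DMSO. Untreated peaks were found with Nutlin-3 in 32 cases (6.45%, 4.45 to 8.99; highest of shuffles 3, of local moves 5), and 34 Nutlin-3 peaks (0.187%, 0.130 to 0.262; 4 and 6) overlapped an untreated peak. With DMSO in place of no treatment as its control, doxorubicin had 1649 regions that the control lacked, against 2911. Ordered by their widest Nutlin-3 peak, the regions found in all 4 lists were led by chromosome 2 from 132728271 to 132730011, chromosome 9 from 67902311 to 67904311 and chromosome 20 from 26136751 to 26137471. The others lay on chromosome 1 from 154452851 to 154453211, chromosome 3 from 199384691 to 199384731 and chromosome 20 from 26137791 to 26138491. The chromosome 2 region overlapped a dense stretch of the untreated list. The regions on chromosomes 9 and 20 lay within 2 Mb of the longest peak-free interval of their chromosome.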

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

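The values outside dense stretches were chosen only after the lists had been compared. Mean peak width moved in opposite directions from control to treatment in the 2 pairs. Doxorubicin minus no treatment was -82.7 bp (112 bp against 195 bp), and Nutlin-3 minus DMSO was 6.99 bp (88.7 bp against 81.7 bp). With 1 list per condition the difference between the pairs was not tested. Outside the dense stretches of the untreated list and chromosomes M and Y the values were -14.8 bp and 6.95 bp, so the first was mostly made by peaks in those places.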

How the results depend on the processing

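The alternatives that left out dense stretches with chromosomes M and Y, exchanged the control or left out a control list, and the random subsets, were chosen only after the data were seen. No number of peaks per list moved by over 1.5 times when peaks within 500 bp were merged (459, 2591, 2888 and 16270 for no treatment, DMSO, doxorubicin and Nutlin-3), and of 78 alternatives for the main results 32 stayed within the interval or within 1.5 times and 46 moved, 19 up and 27 down. The cause was not tested unless stated. With a reciprocal overlap of 50%, no treatment in DMSO gave 0.403% and the reverse 0.0716%, no treatment in doxorubicin 20.4% and the reverse 3.27%, DMSO in Nutlin-3 40.5% and the reverse 6.23%, and doxorubicin in Nutlin-3 33.7% and the reverse 5.73%. Within 1000 bp the values in this order were 4.44%, 0.823%, 39.1%, 7.58%, 88.4%, 18.9%, 78.1% and 19.1%. With midpoints within 200 bp, those of these pairs that moved were no treatment in doxorubicin (29.2%) and the reverse (4.70%), DMSO in Nutlin-3 (84.2%) and the reverse (13.2%), and doxorubicin in Nutlin-3 (75.6%) and the reverse (13.04%).

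Shortening the lists lowered most shares by construction. In the widest 50% of each list, no treatment in doxorubicin gave 39.1% and the reverse 6.55%, DMSO in Nutlin-3 32.7% and the reverse 5.03%, and doxorubicin in Nutlin-3 24.95% and the reverse 4.27%. Random subsets of 50% gave means of 16.9%, 2.77%, 35.3%, 5.45%, 31.9% and 5.43%, so at this length selecting by width raised the sharing of no treatment with doxorubicin and lowered that of doxorubicin with Nutlin-3. With the 496 widest of each list, DMSO in no treatment gave 0.605%, no treatment in doxorubicin 21.8% and the reverse 22.2%, DMSO and Nutlin-3 6.45% in both directions, and doxorubicin and Nutlin-3 3.43% in both. Random sets of 496 gave means of 0.220%, 5.71%, 5.58%, 2.03% and 1.78%, so here the widest exceeded the random mean, but lay within the random range for DMSO in no treatment (highest 0.806%) and doxorubicin and Nutlin-3 (highest 3.63%). Over these alternatives DMSO in doxorubicin ranged from 7.46% (496 widest; random sets 7.18%) to 59.97% (within 1000 bp) and the reverse from 7.26% to 49.3%, with 25.3% and 22.9% under the reciprocal overlap. No treatment in Nutlin-3 ranged from 1.81% (496 widest; random sets 0.194%) to 22.98% (within 1000 bp), with 2.02% under the reciprocal overlap and 9.68% by midpoints, and the reverse from 0.0551% (reciprocal overlap) to 1.81% (496 widest). On autosomes only doxorubicin in Nutlin-3 left its interval (65.8%). Outside the dense stretches and chromosomes M and Y, no treatment in doxorubicin fell to 17.3%, the reverse to 2.24%, doxorubicin in Nutlin-3 rose to 68.2% and doxorubicin in DMSO to 43.8%.

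The 5 region counts stayed within 1.5 times when peaks within 500 bp were merged and outside the stretches. In the widest 50% of each list they were 1441 for doxorubicin without no treatment, 8594 for Nutlin-3 without DMSO, 298 for both treatments and neither control, 411 for both treatments and 109 for DMSO and both treatments; random subsets of 50% gave means of 372, 552 and 178 for the last 3. The regions of both treatments and neither control were 803 without the untreated list and 2168 without the DMSO list, and doxorubicin regions absent from the control were 1649 with DMSO as the control, so these counts depend on the DMSO list. Not run were a common score threshold (no scores), windows around genes and transcription starts and motif settings (no hg18 annotation or genome), and leaving out a replicate (1 library each). Depth is unknown, and a site missing from a list is not shown to be unbound.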

Other observations

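The tests on the share of untreated peaks in dense stretches, on DMSO peaks in neither treatment list and on distances to peak-free intervals were chosen only after the data were seen, as were leaving out the fullest untreated bin or the untreated peaks shared with another list. Positions along the chromosomes set the pairs of libraries apart. Within 2 Mb of the longest peak-free interval of each chromosome lay 19.96% of untreated peaks (95% interval 16.5 to 23.8) and 12.8% of doxorubicin peaks (11.6 to 14.0), against 2.43% of DMSO peaks (1.90 to 3.08) and 2.14% of Nutlin-3 peaks (1.94 to 2.36). The same zones held 4 of the 15 dense stretches of the untreated list, so these shares partly count the stretches again. Shares outside the stretches and a chance level are not given. The doxorubicin list also had 44 peaks between 9 and 10 Mb of chromosome 21, where the other lists had 0. Gaps of at most 500 bp between neighbouring peaks made up 10.4% of gaps with Nutlin-3 (9.98 to 10.9), 7.29% with DMSO (6.35 to 8.32), 6.50% with doxorubicin (5.65 to 7.43) and 7.84% with no treatment (5.58 to 10.6). The ratio of gaps of 100 to 400 bp to gaps of 600 to 900 bp was 5.18 (4.60 to 5.85), 10.7 (6.50 to 18.8), 2.77 (2.06 to 3.78) and 1.41 (0.790 to 2.55) in the same order.

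The control lists shared few peaks, although the labels separate them by a solvent alone. A shorter version of the DMSO list at lower depth is argued against, as 1.21% of untreated peaks overlapped any DMSO peak. Untreated peaks also overlapped 0.605% of the 496 widest DMSO peaks (3 peaks, 95% interval 0.125 to 1.76). That value says less, because width did not rank the sites by how often they were shared. By number of peaks, a list made up mostly of pile-ups in dense stretches or on chromosomes M and Y is also argued against. Of untreated peaks, 30.04% lay in such places (26.0 to 34.3). Mean width was 104 bp outside these places and 195 bp in the whole untreated list. Their share of the covered length was therefore larger, and the argument does not extend to it. Outside chromosomes M and Y the 30.04% counts only runs of at least 5 peaks, so a list made up mostly of isolated pile-ups stays open. Whether the DMSO list comes from a treated culture cannot be told apart from basal binding, since 25.6% of DMSO peaks were in neither treatment list, against 32.4% of doxorubicin peaks in neither DMSO nor Nutlin-3, and no value of a peak list separates these cases. A weaker enrichment in the untreated library and an effect of the solvent stay open and untested, with 1 library per condition.

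Dense stretches of untreated peaks recurred under doxorubicin. Whether p53 binding was the source of the stretches could not be settled. Of the 184 doxorubicin and Nutlin-3 peaks there, 8.15% were Nutlin-3 peaks (15 peaks, 4.63 to 13.1). The Nutlin-3 list is 5.88 times as long as the doxorubicin list, so binding predicted a larger share. However, a library difference between the pairs could lower this share with or without binding, and the stretches were picked from the untreated list. A library or processing difference between the pairs is a candidate explanation. As it predicted, 14 of 15 stretches held a doxorubicin peak, 6 a Nutlin-3 peak and 2 a DMSO peak. These counts largely restate the pattern, so they do not set this explanation above others. The labels give no batch, and the inputs and a repeat annotation were not analysed here, so what made the pairs differ stays open.

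Nutlin-3 peaks gathered in a few 1-Mb bins, led by 44 peaks between 3 and 4 Mb of chromosome 18 and 43 between 123 and 124 Mb of chromosome 12, against a highest bin of 27 in 100 shuffles. The 100 bins fullest in every other Nutlin-3 peak (3.33% of bins) held 13.4% of the remaining Nutlin-3 peaks, 12.2% of DMSO peaks (11.1 to 13.5), 10.4% of doxorubicin peaks and 25.6% of untreated peaks (21.1 to 30.6), the last 2 outside the stretches and chromosomes M and Y; the highest shuffle for untreated peaks was 8.07%. A regional background common to the libraries, such as copy gains or open chromatin, may contribute, since the untreated peaks were the most concentrated there (21.8% without their fullest bin, 29 to 30 Mb of chromosome 8), also among the 265 overlapped by no other list (31.3%, 25.8 to 37.3; 26.9% without that bin). Regional binding that precedes Nutlin-3 cannot be told apart from such a background, because both allow a raised DMSO share. The interval of that share, 12.2%, includes the Nutlin-3 value, which itself comes from neighbours of the peaks that chose the bins. Copy number and accessibility were not measured in these data.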
